A study of Mus musculus with 7 samples.

How the data were processed

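Single-cell RNA sequencing was done on cells sorted by fluorescence from the hypothalamus of mice at postnatal day (P) 8, 17 and 45. Per the labels, the sort kept cells positive for green fluorescent protein (GFP), which a Rax-CreER driver switches on in tanycytes through a Cre-dependent Sun1-GFP reporter. Tanycytes are radial glia-like cells that line the third ventricle, and the progeny of a labelled tanycyte keeps the reporter. Animals labelled KO also carried floxed alleles of the genes for the nuclear factor I transcription factors Nfia, Nfib and Nfix. There were 3 control libraries (1 per age) and 4 libraries labelled KO (1 at P8, 1 at P17 and 2 at P45).

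The deposited matrix holds raw UMI counts, whole numbers of molecules per gene and cell, with no normalization. Per the labels' protocols and the submitters' processing notes, the libraries were made with 10x Genomics 3′ chemistry and processed with Cell Ranger 3.1, and the notes also name Seurat (version not given) and the mm10 mouse genome build. The matrix covers 20889 genes, of which 20866 had at least 1 UMI, in 54470 cells with 376933751 UMIs in all. No matrix column was left unmatched to a library (0 columns). Every cell had between 601 and 5998 detected genes and at most 8.00% of its UMIs from mitochondrial genes, so the authors had filtered the cells before deposit. How doublets were treated before deposit is not given in the sources used here. A table deposited by the authors gives 1 of 9 cell type names to each cell: alpha1, alpha2, beta1 and beta2 tanycytes, proliferating tanycytes, neurons, astrocytes, ependymal cells and oligodendrocyte precursor cells (OPCs). These names were used unchanged. How they were assigned, and whether genes that differ between the genotypes took part, is not given in the sources used here.

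Cells are not replicates, so raw counts were summed per library over the cells of a class, and the sums were tested with edgeR 4.0.16 in R 4.3.3. The settings were TMM normalization, filterByExpr with its count minimum of 10, robust dispersion estimates, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. A gene is said to rise or fall only if its adjusted p was under 0.05. A standard error (SE) is the log2 fold change divided by the square root of the F statistic. Levels are CPM, a gene's share of the summed counts times 1e6, given as mean ± SD over libraries. The control SD spans 3 ages and so holds age differences as well as noise. Tanycytes were the 5 annotated tanycyte classes together, 35109 cells.

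The genotype effect was fitted over all 7 libraries with age as a factor (3 residual degrees of freedom), in tanycytes and in each annotated type with at least 20 cells in every library, which held for 4 tanycyte subtypes and for astrocytes. The change of that effect with age was the coefficient of genotype times log2 of the postnatal day (2 residual degrees of freedom). The age effect in tanycytes was P45 minus P8 adjusted for genotype. In neurons of the 4 libraries labelled KO, the coefficient of log2 postnatal day was tested (2 residual degrees of freedom). Numbers of cells per annotated type were tested with edgeR's quasi-likelihood test with the library's total cells as library size. An exact two-sided permutation of genotype within age was set beside it, with 12 arrangements and a smallest possible p of 0.0833. Shares per library carry exact Clopper-Pearson 95% intervals, which cover counting error only, as does the floor of 3 counts used where a gene had 0 counts in every control library. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these libraries. Only KO P45 has 2 libraries, and no control group is replicated. Most residual degrees of freedom of the genotype test therefore come from differences of the genotype effect between ages.

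Gene lists were tested in limma 3.58.1 with camera at a preset correlation of 0.01 on log2 CPM (prior count 2), with an estimated correlation and with fry beside it, each adjusted by Benjamini-Hochberg over the lists. The lists were: NFI family, tanycyte core, alpha tanycyte, beta tanycyte, neural stem and radial glia, Notch receptors and effectors, Sonic hedgehog pathway, Wnt pathway, BMP and TGF-beta pathway, S phase, G2 and M phase, proneural and neuronal precursor, pan-neuronal, GABAergic, glutamatergic, neuropeptide and monoamine, hypothalamic neuron transcription factors, astrocyte, ependymal, oligodendrocyte precursor, oligodendrocyte, microglia and macrophage, endothelial, mural and fibroblast, pars tuberalis and pituitary, erythroid, dissociation and immediate early, interferon response, mitochondrially encoded and sex-linked. The alpha and beta tanycyte lists share most of their genes with the tanycyte core list. Lists with under 2 tested members were not put to camera.

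The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took Nfia, Nfib and Nfix, then the 12 genes with the largest rise and the 12 with the largest fall in tanycytes. These had to pass the test, reach a mean CPM of 30 and lie on the same side of the control library of their own age in every library labelled KO. Predicted, mitochondrial and ribosomal protein genes were left out. For the age effect, where the direction had to be shared by both genotypes, and the change of the genotype effect with age 8 and 8 genes were taken, and 5 and 5 for subtypes, astrocytes and KO neurons. Where fewer than 6 passed in a direction, the list was filled by lowest p, and the text gives these as not passing. From each gene list up to 4 called members with the smallest p were named, or up to 2 of the highest CPM where none was called. In KO neurons the 8 members of the neuron-type lists with the highest CPM were added. Other genes are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

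Doublets were called per library with Scrublet as run in scanpy 1.11.5 (Python 3.11.15) at an expected rate of 0.06, and were kept in the reported values. It called 2580 cells (4.74%). In the control P45 library it called only 7 of 2607 cells, so there it may have missed doublets. The 2 KO P45 libraries differed by more than sampling noise (chi-square per degree of freedom 21.4 over 14273 genes) and were kept as separate samples. Gene positions are from GENCODE M21 on mm10, counted from 1.

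The gene test was tried in 6 comparisons on simulated counts drawn from the real means, with 200 genes changed. The alpha1, beta1 and beta2 tanycyte comparisons and the test of shares were not simulated. For tanycytes, KO against control, over 16124 genes, 72.0% of genes changed by log2 1 and 98.0% of those changed by log2 2 were called, and 8.11% of the calls were false, above the nominal 0.05. For the change of the genotype effect with age the recovered shares were 24.0% and 92.0% (4.92% of calls false), for P45 against P8 60.0% and 99.0% (8.62% of calls false), for KO neurons with age over 14186 genes 73.0% and 100% (4.95% of calls false) and for astrocytes over 11046 genes 61.0% and 99.0% (6.98% of calls false). For alpha2 tanycytes over 14173 genes they were 82.0% and 98.0%, with 10.9% of calls false. Camera called 5 of 5 simulated shifted lists and 0 of 15 unshifted ones. The genes of these lists were picked at random and their counts drawn independently. The simulation therefore cannot show how often camera calls lists falsely where genes are correlated, as in the real lists.

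Alternatives were other scalings (DESeq2's size factors, total counts), no filter on low counts, the DESeq2 1.42.0 Wald test, limma voom, leaving out each library in turn, leaving out called doublets, only cells with at least 2000 UMIs, equal numbers of cells per library, equal subtype proportions, no age term, limma on logit-transformed shares, leaving out genes that ambient RNA from another type could supply, and age rank in place of log2 day. Leaving out proliferating tanycytes, the list test without called doublets, the age interaction of the shares and a minimum of 10 cells for further cell types were added after seeing the data.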

Results

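The data were 7 libraries of GFP-sorted hypothalamic cells from control mice and from mice labelled KO for Nfia, Nfib and Nfix, at P8, P17 and P45. The control libraries held 6609 (P8), 6494 (P17) and 2607 (P45) cells. The libraries labelled KO held 12930 (P8), 12413 (P17), 7531 (P45 replicate 1) and 5886 (P45 replicate 2) cells. Total UMIs were 44200047, 48743557 and 28081032 in the control libraries in order of age, and 87241941, 89824059, 33014995 and 45828120 in the KO-labelled ones. The median per cell ranged from 3839 UMIs in KO P45 replicate 1 to 10371 in control P45.

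Transcripts of the targeted genes were counted in tanycytes first. All 3 were higher in the libraries labelled KO. Nfia stood at 389, 248 and 242 CPM in the control libraries at P8, P17 and P45, and at 647, 755, 571 and 642 CPM in KO P8, P17 and P45 replicates 1 and 2. Nfib stood at 507, 372 and 426 CPM against 827, 892, 868 and 731 CPM. Nfix stood at 615, 477 and 601 CPM against 932, 1075, 983 and 957 CPM. The log2 fold changes were 1.31 ± 0.19 (SE) for Nfia, 1.03 ± 0.15 for Nfib and 0.89 ± 0.14 for Nfix, with edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.00515, 0.00515 and 0.00665. Nfic, which was not targeted, lay between 96.7 and 116 CPM in the KO-labelled libraries and between 121 and 151 CPM in controls, and did not pass the test. The 3 targeted genes thus showed no loss of transcripts in the libraries labelled KO. The libraries count 3′ tags, and a tag outside the deleted part checks nothing. Which exons were floxed is not given in the sources used here, so these counts can check neither the deletion nor the labels. Nfia spans chromosome 4 from 97772734 to 98118874 (plus strand), and its last exon, 98111218 to 98118874, is nearly all 3′ UTR (from 98111233). Nfib spans chromosome 4 from 82290173 to 82705750 (minus strand), with its last exon from 82290173 to 82296811. Nfix spans chromosome 8 from 84699876 to 84800344 (minus strand), with a last exon from 84704712 to 84708677. Directions for KO below are those of the libraries labelled KO.

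**Figure D1:**
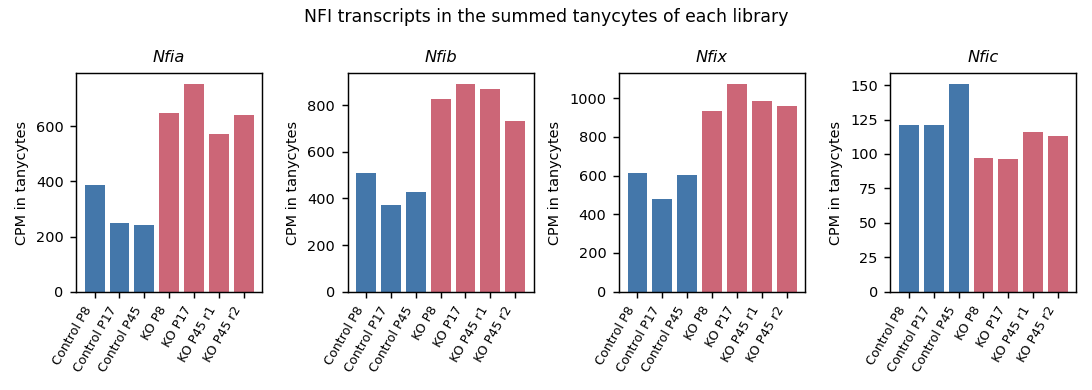
Transcript level of each NFI family gene in the summed tanycytes of each library, in CPM (y axis), with control libraries in blue and KO-labelled libraries in red. Nfia, Nfib and Nfix are higher in each of the 4 KO-labelled libraries than in each control library, and Nfic is not.

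The makeup of the sorted cells addressed whether labelled tanycytes gave rise to other cell types. Neurons, cells that the reporter marks only if they or a precursor had expressed the driver, made up 7.96% (95% interval 7.32 to 8.64), 0.678% (0.493 to 0.909) and 0.460% (0.238 to 0.803) of control cells at P8, P17 and P45. In the libraries labelled KO they made up 13.6% (13.1 to 14.2) at P8, 56.0% (55.1 to 56.8) at P17, and 49.8% and 51.4% in the 2 P45 replicates. Proliferating tanycytes made up 1.95%, 0.123% and 0.153% of control cells and 11.8%, 9.66%, 8.10% and 5.42% of KO-labelled cells. Alpha1 tanycytes were fewer, with 13.2%, 10.1% and 16.99% against 8.87%, 2.76%, 3.19% and 3.98%, and so were astrocytes, with 3.81%, 9.72% and 11.6% against 2.02%, 2.21%, 2.11% and 2.65%. The log2 ratios were 5.18 ± 1.48 (SE) for neurons, 4.78 ± 0.93 for proliferating tanycytes, -1.66 ± 0.55 for alpha1 tanycytes and -1.85 ± 0.54 for astrocytes. The edgeR quasi-likelihood adjusted p were 0.0232, 0.00528, 0.0338 and 0.0232. The 4 called types moved in the same direction at every age.

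The other 5 of the 9 types did not pass: alpha2 tanycytes (log2 ratio -0.63, edgeR adjusted p = 0.292), beta1 tanycytes (-1.08, adjusted p = 0.0926), beta2 tanycytes (-1.29, adjusted p = 0.0926), OPCs (-1.48, adjusted p = 0.0926) and ependymal cells (-0.66, adjusted p = 0.413). All tanycytes together were 85.3%, 88.1% and 83.1% of control cells and 79.7%, 40.8%, 47.0% and 45.3% of KO-labelled cells. The exact permutation p was 0.0833, the smallest the design allows, for all types but ependymal cells (exact permutation p = 0.667). A share depends on every other share and on the GFP gate, and cells lost or gained in the sort cannot be seen. No type passed without the control P17 or the KO P17 library (0 called of 9 by edgeR), only proliferating tanycytes passed without the control P45 library, and neurons and proliferating tanycytes alone without either KO P45 library. Without the control P8 or KO P8 library 7 passed. The log2 ratio of OPCs was -0.33 without control P45, that of alpha2 tanycytes -0.37 without either P17 library, and that of ependymal cells -1.44 without either P8 library, -0.19 without KO P45 replicate 2 and, with the direction turned, 0.57 without control P45.

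**Figure D2:**
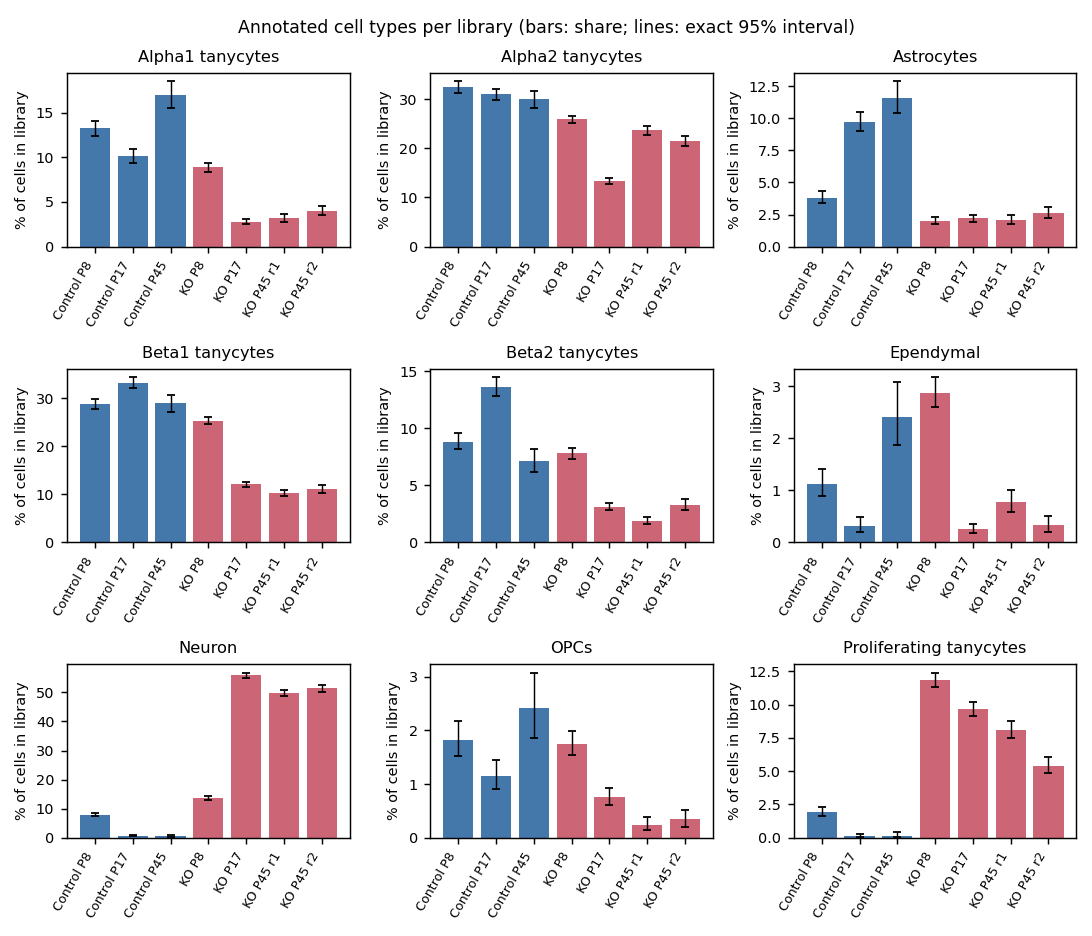
Share of each annotated cell type in percent of the library's cells (y axis), with control libraries in blue, KO-labelled libraries in red and lines for the exact 95% interval. Neurons reach 49.8% to 56.0% in the KO-labelled P17 and P45 libraries and stay under 1% in the controls of those ages.

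Tanycyte expression was compared between KO-labelled and control libraries, averaged over ages. Among called genes with a mean of at least 30 CPM and a change in the same direction in every KO-labelled library, the largest rise was that of Fst, which encodes the activin antagonist follistatin, at 1.62 ± 1.76 CPM (SD, n = 3) in controls and 165 ± 84.1 CPM (n = 4) in the KO-labelled libraries, a fitted 101-fold rise. Lmo2, a LIM-domain transcription cofactor, rose 36.1-fold. The other 10 of the 12 largest rises among these genes were cell division genes: Mki67, Pbk, Ube2c, Top2a, Ccnb2, Cdk1, Pclaf, Birc5, Cdca3 and Cdca8, from 30.2-fold (Cdca8) to 52.5-fold (Mki67). The largest falls among them were Clec3b, which encodes tetranectin, from 346 ± 52.8 to 11.6 ± 14.2 CPM (43.3-fold lower), the retinol carrier Rbp4 (26.2-fold lower), S100a4 (11.8-fold lower) and the protease gene Htra1 (10.5-fold lower). Genes typical of astrocytes fell as well: Aldoc from 1446 ± 458 to 139.6 ± 56.7 CPM, Gfap 9.89-fold, the glutamate transporter Slc1a2 9.44-fold and Clu 9.26-fold. Tgfb2 (9.54-fold lower), Cmtm5 (9.14-fold), Ppp1r3c (9.05-fold) and Mia (8.42-fold) complete the 12. For the 24 genes, which were chosen for a shared direction in the KO-labelled libraries, the edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) ranged from 0.000676 (S100a4) to 0.0474 (Ube2c).

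In all, 5260 of 16124 genes passed edgeR's quasi-likelihood test, 2655 higher and 2605 lower. The count fell to 1697 without the control P17 library, 1142 without control P45, 1673 without KO P17, 2527 without KO P45 replicate 1 and 2965 without replicate 2. Of the named genes, the calls of 61 ended without control P17 and of 61 without KO P17, with Fst, Shh, Lmo2, Mki67 and Gfap in both sets and Clec3b in the control P17 set. Calls also ended for 48 without control P45 (Mki67, Dio2 and Tubb3 among them), 35 without KO P45 replicate 1, 22 without replicate 2, 13 without a filter on low counts, 12 without the age term and 11 with equal subtype proportions (Birc5 and Ppp1r3c among them). Without proliferating tanycytes Cdca8 stood at 2.17, Cdca3 at 2.19, Cdk1 at 1.95 and Birc5 at 1.69, and Pclaf lost its call.

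**Figure D3:**
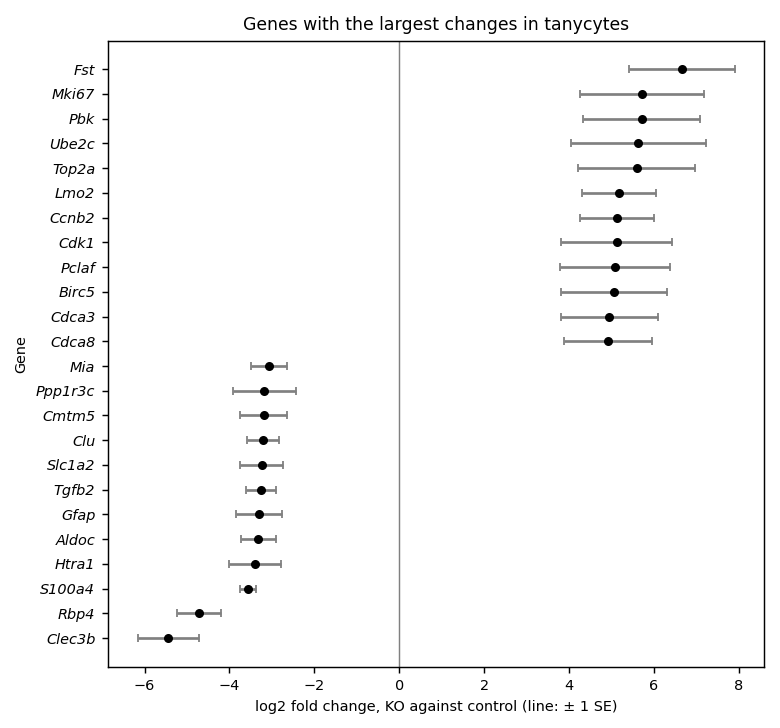
Log2 fold change of tanycyte expression, KO-labelled against control (x axis), for the 12 genes with the largest rise and the 12 with the largest fall among those with a mean of at least 30 CPM (y axis), with lines for ± 1 SE. Fst rises by 6.66 and Clec3b falls by 5.44 on the log2 scale.

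Genes of the cell cycle rose together. All 17 S phase genes rose, among them Tyms (log2 fold change 2.32), Mcm6 (1.57), Mcm7 (1.47) and Mcm2 (2.86), of the replication machinery. All 18 G2 and M phase genes rose, among them Ccnb2 (35.0-fold), Cdc20 (21.3-fold), Nusap1 (19.2-fold) and Tpx2 (19.1-fold). The counts were also 17 and 18 when adjusted over the list alone. Camera's adjusted p was 5.32e-10 for S phase and 2.72e-08 for G2 and M phase, and both were lost with an estimated correlation (adjusted p = 0.532 each). Cells annotated as proliferating are part of these sums and were 1.95% or less of control cells and 5.42% or more of KO-labelled cells. Without them 20 of the 35 genes were still called higher, and the median log2 fold change was 3.58 over the 35 genes and 0.99 over the 34 still tested. Nusap1 (log2 fold change 0.29) lost its call there, and Tyms stood at 0.45, Mcm6 at 0.45, Mcm7 at 0.74, Tpx2 at 1.02, Cdc20 at 1.17, Top2a at 2.50 and Ccnb2 at 2.70. With equal subtype proportions Birc5 (1.92), Mcm6 and Nusap1 (0.41 each) lost their calls. There Tyms stood at 0.51, Mcm7 at 0.70, Tpx2 at 1.03, Cdc20 at 1.18, Pclaf at 1.64, Mcm2 at 1.88, Cdk1 at 1.96, Cdca8 at 2.10, Cdca3 at 2.35, Top2a at 2.66 and Ccnb2 at 3.11.

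Tanycyte marker genes fell. Of 17 tanycyte core genes 13 fell, 0 rose and 4 did not pass (15 fell when adjusted over the list alone), including Cd59a (3.62-fold lower), the vesicular glutamate transporter Slc17a8 (3.93-fold), the collagen Col23a1 (783.6 ± 87.1 against 225.7 ± 126 CPM, n = 3 and 4) and the growth factor Fgf10 (2.53-fold). The beta tanycyte list had 6 of 8 members lower (8 adjusted over the list alone), with Adm (log2 fold change -2.71), Dio2 (-2.88), which activates thyroid hormone, and Penk (-4.09). The alpha tanycyte list had 3 of 4 lower (3 adjusted over the list alone), with Cd59a, Slc17a8 and Crym (1.41-fold). Camera's adjusted p was 9.33e-05 for the core list and 0.00154 for the beta list, and 0.0601 for the alpha list. All 3 had adjusted p = 0.532 with an estimated correlation. Astrocyte genes fell in 12 of 12 cases (12 adjusted over the list alone), among them Atp1b2, Gja1 and Slc6a11 by 1.20, 1.63 and 1.36 on the log2 scale, and ependymal genes in 6 of 12 (9 adjusted over the list alone), with Dynlrb2, Rarres2, Mia and Rsph1 falling by 1.53, 2.45, 3.07 and 1.35. Camera's adjusted p was 8.00e-06 for the astrocyte and 0.000932 for the ependymal list, and 0.532 for both with an estimated correlation. With equal subtype proportions Slc17a8 and Fgf10 stood at -1.17 and -0.87 and Crym (-0.23) lost its call.

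Neuronal genes rose. Of 12 tested proneural and neuronal precursor genes 7 rose and 1 fell (10 and 1 adjusted over the list alone): Sox4 (3.15-fold), Mfng (46.5-fold) and Neurod1, which had 0 UMIs in the controls and was at least 26.9-fold higher against a floor of 3 counts over the group, while Gadd45g fell 3.37-fold. Of 12 pan-neuronal genes 7 rose (9 rose and 1 fell adjusted over the list alone), including the imprinted noncoding RNA Meg3 (977.6 ± 207 against 5204 ± 1526 CPM, n = 3 and 4), Map2, Tubb3 and Elavl3 (log2 fold changes 0.58, 3.17 and 2.65). Of 8 GABAergic genes 3 rose (4 adjusted over the list alone), Dlx5, Slc32a1 and Dlx6, at means of 1.54, 3.29 and 0.702 CPM in KO-labelled tanycytes. Of 14 hypothalamic neuron transcription factors 8 rose and 1 fell (8 and 1 adjusted over the list alone), with Isl1 (37.8-fold), Foxp2 (4.81-fold), Hmx3 (18.4-fold) and Hmx2, at 0 UMIs in controls and at least 24.1-fold higher. Camera's adjusted p was 0.000932 for the first 3 of these lists and 0.00163 for the transcription factors, with adjusted p = 0.532 for all 4 with an estimated correlation. Neurons were up to 56.0% of the cells of the same libraries. Neuron-specific transcripts were those over 20-fold lower in control tanycytes than in KO-labelled neurons. The 50 most abundant of them stood in KO-labelled tanycytes at a median of 6.45% to 12.5% of their level in the neurons of the same library. Without called doublets Dlx5 (1.62), Slc32a1 (2.44) and Neurod1 lost their calls. Slc32a1, Dlx6 and Slc17a6 stood at 6.87, 4.39 and 6.90 without control P8 and at 6.83, 4.34 and 6.84 without KO P8, and Dlx6 lost its call at 1.87 and 1.88 without control or KO P17. The only tested glutamatergic gene, Slc17a6, rose from 0.0442 to 1.24 CPM. Of 18 neuropeptide and monoamine genes 2 rose, Gal (7.09-fold) and Ddc (9.25-fold), and 2 fell, Ghrh (2.01-fold) and Penk (2 and 2 adjusted over the list alone; camera adjusted p = 0.296, and 0.612 with an estimated correlation).

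Signalling lists held members that moved in both directions. Shh, which encodes the Sonic hedgehog ligand, rose from a mean of 4.96 CPM (1.51 to 6.94, n = 3) to 124 CPM (67.4 to 188, n = 4), with a log2 fold change of 4.63 ± 0.76 (SE) and an edgeR adjusted p of 0.0125. Gas1 (2.75-fold), Boc (1.71-fold), both coreceptors of the pathway, and Gli2 fell, and 1 further member rose (2 rose and 3 fell of 12; 2 and 4 adjusted over the list alone). That member was Gli3 (log2 fold change 0.54), named after its value was seen. In the Notch list 3 of 12 rose and 2 fell (3 and 2 adjusted over the list alone): the feedback inhibitor Nrarp (log2 fold change 1.59) and the receptor Notch3 (2.89) rose and Hey2 (-1.72) and Lfng (-0.99) fell. The other, Hes5 (log2 fold change 2.46), was named after its value was seen. In the Wnt list 4 of 14 rose and 2 fell (5 and 3 adjusted over the list alone), with the secreted antagonists Sfrp1 (2.33-fold) and Sfrp2 (2.74-fold) higher and the feedback target Axin2 (1.72-fold) and Dkk3 (1.83-fold) lower. In the BMP and TGF-beta list 3 of 15 rose and 3 fell (3 and 3 adjusted over the list alone), with Id4, Tgfb2 and Bmpr1b lower (log2 fold changes -1.21, -3.25 and -2.13) and Smad7 higher (1.73-fold). Sfrp2 stood at 0.88 without control P45, and Msi1 at 0.39 with equal subtype proportions. Neural stem and radial glia genes rose in 3 and fell in 2 of 11 cases (4 and 3 adjusted over the list alone): Fabp7, Msi1 and Sox2 rose (log2 fold changes 2.07, 0.58 and 0.57) and Slc1a3 fell (-0.99). None of these 5 lists was called by camera (adjusted p from 0.481 for Wnt to 0.981 for BMP and TGF-beta), nor with an estimated correlation (adjusted p from 0.628 to 0.986).

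The NFI family list had 3 of 4 members higher (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0970, and 0.532 with an estimated correlation). Among markers of other cell types, oligodendrocyte precursor genes fell in 2 of 7 cases, Olig1 (6.45-fold) and Olig2 (9.32-fold), and oligodendrocyte genes in 2 of 7, Cnp (2.56-fold) and Mag (2.57-fold), with camera adjusted p of 0.114 and 0.115 (adjusted p = 0.532 for both with an estimated correlation). Endothelial genes fell in 3 of 5 cases, Slco1a4 (13.4-fold), Itm2a (2.42-fold) and Flt1 (4.21-fold), with camera adjusted p = 0.0441, and adjusted p = 0.532 with an estimated correlation. Dcn, of 7 mural and fibroblast genes, fell 3.52-fold (camera adjusted p = 0.501), and the microglia and macrophage list was not called (camera adjusted p = 0.542). Hba-a1, of 2 erythroid genes, rose from 0 UMIs, at least 21.5-fold (camera adjusted p = 0.383). Adjusted over the list alone the counts were 2, 2, 3 and 1 for the oligodendrocyte precursor, oligodendrocyte, endothelial and mural lists and, for erythroid genes, 2. Dissociation and immediate early genes fell in 5 of 16 cases (6 adjusted over the list alone; camera adjusted p = 0.0141, and adjusted p = 0.612 with an estimated correlation), among them Socs3 (3.22-fold), Zfp36 (2.58-fold) and Nr4a1 (1.42-fold). Hspa1a fell 1.56-fold, but it has a near-identical copy, Hspa1b, and is uncertain. Interferon response genes fell in 4 of 10 cases (6 adjusted over the list alone; camera adjusted p = 0.0108, and adjusted p = 0.532 with an estimated correlation), among them Ifitm3 (2.39-fold), Ifit1 (2.90-fold) and Ifi27 (1.76-fold). The mitochondrially encoded genes mt-Nd2 (1.47-fold) and mt-Nd1 (1.75-fold) rose, 2 of 13 (0 adjusted over the list alone; camera adjusted p = 0.0947). No sex-linked gene passed edgeR's test (0 of 5, and 0 adjusted over the list alone; camera adjusted p = 0.981); Xist stood at 563 and 978 CPM and Ddx3y at 50.9 and 39.5 CPM on average in controls (n = 3) and KO-labelled libraries (n = 4). Of the pars tuberalis and pituitary list only Cga was tested (log2 fold change 6.20, edgeR adjusted p = 0.0892, not called). The endothelial call was lost without control P8, control P17, control P45 or KO P45 replicate 2 and with total counts (camera adjusted p = 0.0696), and the dissociation call without either P17 library, control P8 or KO P8. With fry the adjusted p were 0.0621 and 0.245. Hba-a1 lost its call without control P8 (4.02), control P17, control P45 or KO P17, with DESeq2 (4.45), limma voom (3.55) or total counts, without a filter and with only cells of at least 2000 UMIs, and Olig2 (-0.80) without proliferating tanycytes, where Olig1 stood at -1.49. Olig1 (-1.27) and Nr4a1 (-0.22) lost theirs with equal subtype proportions, and Hspa1a (-0.34) without the age term.

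**Figure D4:**
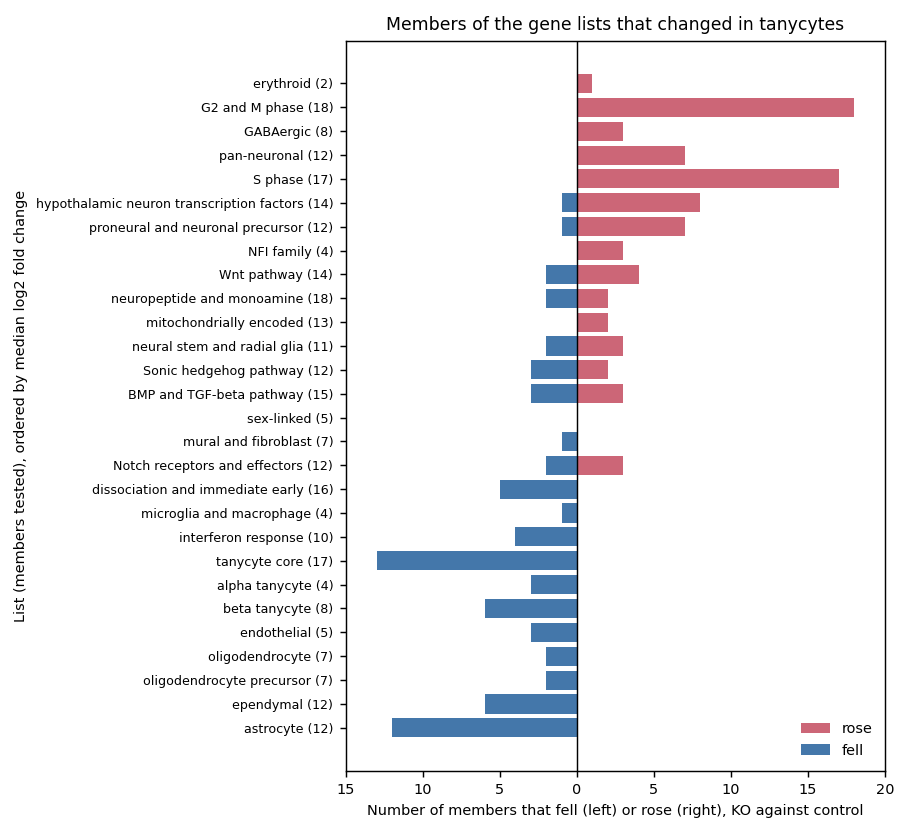
Number of members of each gene list that fell (left, blue) or rose (right, red) in tanycytes of the KO-labelled libraries, with the number tested in brackets. All 17 S phase and 18 G2 and M phase genes rose, and all 12 astrocyte genes fell.

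The same contrast within each annotated subtype asked whether the changes hold when subtype proportions are set aside. Clec3b fell in each of the 4 subtypes, by 2.84 (alpha1), 6.88 (alpha2), 5.10 (beta1) and 6.04 (beta2) on the log2 scale. In alpha1 tanycytes the imprinted gene Dlk1 rose 69.7-fold, with Tubb3 (13.7-fold), Prss23 (13.4-fold), Meg3 (7.59-fold) and Ncald (7.56-fold), while Aldoc (log2 fold change -3.04), Gsn (-2.92), S100a4 (-2.73) and Tgfb2 (-2.59) fell. In alpha2 tanycytes Dlk1 rose 184-fold, Fst 89.1-fold, Shh 67.3-fold, Prss23 38.6-fold and Sfrp2 21.2-fold, and Adcy2 (-4.40), Aldoc (-4.12), Flt1 (-4.12) and Ecel1 (-4.11) fell. In beta1 tanycytes Lmo2 rose by 5.98 log2 units, Shh by 4.11, Prss23 by 3.92, Calb1 by 3.75 and Igfbp2 by 3.46, and Rbp4, Slc1a2, Slco1c1 and Gfap fell 16.8-, 11.6-, 11.1- and 10.5-fold. In beta2 tanycytes Fam159a (12.8-fold), Snhg11 (8.09-fold), Pcp4 (8.03-fold), Dlk1 (6.04-fold) and Stra6 (5.14-fold), a retinol transporter, rose, and Ppp1r1b, Gas6, A2m and Tmem52 fell 14.7-, 9.94-, 6.02- and 5.84-fold. Levels of these genes are sums over 140 (beta2, KO P45 replicate 1) or more cells per library.

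By edgeR's quasi-likelihood test 1824 of 12980 genes passed in alpha1, 4549 of 14173 in alpha2, 3063 of 14141 in beta1 and 1684 of 12110 in beta2 tanycytes. Their adjusted p for the named genes ranged from 2.42e-06 (Gsn in alpha1) to 0.0494 (Slco1c1 in beta1). Counts fell by over 1.5 times without either P17 library (670, 1684, 1296 and 758 without control P17; 695, 1707, 1303 and 767 without KO P17), without control P45 (761, 1226, 1071 and 606), without KO P45 replicate 1 in alpha1, alpha2 and beta1 (992, 2214 and 1653) and without replicate 2 in alpha2, beta1 and beta2 (2468, 1657 and 1051). Of the 10 named genes in each of alpha1, alpha2, beta1 and beta2, the calls of 4, 5, 9 and 4 ended without control P17 and of 5, 4, 7 and 4 without KO P17. Without control P45 they ended for 0, 1, 5 and 2, without KO P45 replicate 1 for 1, 1, 5 and 3, and without a filter on low counts for 5, 2, 5 and 0. Only Rbp4 kept its call in beta1 without control P17, and it lost it without control P45. Slc1a2, Calb1 and Slco1c1 lost theirs in beta1 in all 5 of these settings. Clec3b lost its call without either P17 library in alpha1, beta1 and beta2, without control P45 in beta1 and beta2, and without a filter in alpha1. Without either P17 library Dlk1 lost its call in alpha1 and alpha2, Fst in alpha2 and Shh in beta1, and Shh lost it in alpha2 and beta1 without either P8 library. Clec3b stood at -9.77 and -9.76 in beta2 without control or KO P8. In alpha1 the count rose to 2799 without control P8 and 2810 without KO P8. Nfia and Nfib rose in all 4 subtypes, and Nfix in all but beta2 tanycytes (log2 fold change 0.36, edgeR adjusted p = 0.112).

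How the genotype effect changed with age was tested per doubling of the postnatal day. Cell division genes had a larger KO-labelled to control ratio at later ages: Pbk by 3.98 ± 0.32 (SE) log2 units per doubling, Mki67 by 3.91 ± 0.49, Ube2c by 3.73 ± 0.19, Cdk1 by 2.89 ± 0.34, Spc25 by 2.28 ± 0.29, Prc1 by 2.12 ± 0.25 and Lockd, a noncoding RNA, by 1.58 ± 0.17. Proliferating tanycytes were 1.95%, 0.123% and 0.153% of control cells by age (129, 8 and 4 cells). In the KO-labelled libraries they were 11.8%, 9.66%, 8.10% and 5.42%. Neurons dilute these shares, and this contrast was tested in tanycytes only. Of tanycytes alone, proliferating ones were 2.29%, 0.14% and 0.185% in controls by age. In KO P8, P17 and P45 replicates 1 and 2 they were 14.8%, 23.7%, 17.2% and 11.97% of tanycytes. After P8 this share thus fell in controls. In the KO-labelled libraries it was higher at P17 and in P45 replicate 1 and lower in replicate 2. With the fall in controls, a growing ratio need not mean more division with age. The cell adhesion gene Opcml changed by 1.44 ± 0.19. The ratio fell with age for Kcne1l (-1.03 ± 0.10) and for the bicarbonate transporter Slc4a4 (-0.79 ± 0.10). The edgeR quasi-likelihood adjusted p ranged from 0.00440 (Ube2c) to 0.0483 (Opcml). Slc1a2 (-1.01), Timp4 (-0.82), Clu (-0.79) and Rasgrp1 (-0.69) did not pass (edgeR adjusted p from 0.0558 to 0.0774).

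In all 50 of 16124 genes passed, 41 with a positive and 9 with a negative coefficient. By list, 5 of 18 G2 and M phase genes (17 adjusted over the list alone) and 3 of 8 GABAergic genes (7 adjusted over the list alone), namely Dlx2, Dlx6os1 and Gad1, had positive coefficients. For these lists the camera adjusted p were 1.35e-15 and 0.000261, and with an estimated correlation the adjusted p were 0.535 and 0.585. Neurons made up 13.6% of the cells in KO P8 and 49.8% to 56.0% in the later KO-labelled libraries, against 7.96%, 0.678% and 0.460% in the controls, and RNA from neurons was not tested for this contrast. The count was 1 with limma voom, 360 with DESeq2 and 92 without a filter, 107 with age rank, and by edgeR 292 and 291 without control or KO P8, 1447 and 1450 without control or KO P17, 1312 without control P45 and 9 without KO P45 replicate 2. Without proliferating tanycytes all 8 named genes with a positive coefficient lost their call: the coefficient shrank to 0.55 for Pbk, 1.12 for Mki67, 1.67 for Ube2c, 0.65 for Cdk1, 0.24 for Spc25, 0.74 for Prc1 and 0.63 for Lockd, and was 1.45 for Opcml. With limma voom all named genes but Ube2c lost theirs, and without KO P45 replicate 2 all but Pbk, Mki67 and Ube2c. Without control P8 the coefficients of Mki67, Pbk, Cdk1, Spc25 and Opcml were 2.05, 2.59, 1.61, 1.35 and 0.95, and without KO P8 2.04, 2.57, 1.60, 1.34 (Spc25, call lost) and 0.95.

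Between P8 and P45, averaged over genotypes, tanycytes gained interferon response transcripts. Transcription factor genes were among the largest falls, but they were not tested as a group. Interferon response genes rose in 5 of 10 cases (8 adjusted over the list alone), among them Oasl2, Ifit1, Isg15 and Usp18, by 3.15, 2.43, 2.87 and 1.83 on the log2 scale. Among genes with a mean of at least 30 CPM, the larger rises included the receptor Gpr37l1 (3.51-fold), Tmx2 (3.27-fold), the glutamate receptor Gria1 (log2 fold change 1.59), the prion protein gene Prnp (1.47), Por (1.43) and Cox6b2 (1.40). The chaperone genes Hspa1a (16.5-fold) and Hspa1b (31.5-fold) rose most among these genes, and as near-identical copies their separate values are uncertain. The largest falls at that level were Nfatc2 (9.61-fold), the transcription factor genes Maff (4.19-fold), Creb5 (3.64-fold) and Nr4a1 (3.19-fold), the cold-inducible Rbm3 (3.66-fold), Sorcs2 (3.42-fold), Rasl11a (3.34-fold) and Lmna (3.33-fold), which encodes lamin A. For these 16, which were chosen for a shared direction in both genotypes, the edgeR quasi-likelihood adjusted p ranged from 0.00115 to 0.0454. Hspa1a and Hspa1b, which rose, and Nr4a1, which fell, belong to the dissociation and immediate early list. Whether a difference in dissociation between the ages accounts for them was not tested.

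In all, 437 of 16124 genes passed, 203 higher and 234 lower at P45. The interferon list had a camera adjusted p of 5.10e-08, and 0.455 with an estimated correlation. The count depended on single libraries: by edgeR it was 2 without control P45, 3 without KO P45 replicate 1, 0 without KO P45 replicate 2 (2742 genes at an unadjusted p under 0.05), 193 and 173 without the control or KO P17 library, 878 without control P8 and 1791 without KO P8. It was 1803 with DESeq2 and 980 without proliferating tanycytes. Sorcs2 and Rasl11a lost their calls without either P17 library and with total counts. All 16 genes lost theirs without KO P45 replicate 2, all but Nfatc2 and Hspa1a without control P45, and all but these and Hspa1b without replicate 1. Rasl11a stood at -1.15 without KO P8.

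Neurons of the KO-labelled libraries were followed from P8 to P45 to see whether their transcripts changed with age. The peptide gene Cartpt rose by 2.52 ± 0.19 (SE) log2 units per doubling of the postnatal day, with TMM-scaled levels of 8.07 CPM at P8, 26.3 CPM at P17, and 489.9 and 520.5 CPM in the 2 P45 libraries, and Sst, which encodes somatostatin, by 1.76 ± 0.12. Cox6a2 (1.68 ± 0.10) and Snhg11 (1.44 ± 0.16) rose too, as did the uncertain Hspa1a (1.89 ± 0.23). The peptide gene Npy fell (-1.34 ± 0.15), as did Crym (-1.32 ± 0.18), Fabp7 (-1.30 ± 0.18), the Notch effector Hes5 (-1.30 ± 0.17) and the cell cycle inhibitor Cdkn1c (-1.17 ± 0.09). Tanycytes were 79.7% of the cells in KO P8, 40.8% in KO P17, and 47.0% and 45.3% in the 2 KO P45 libraries. The tanycyte gene Rax was seen in a larger share of KO P8 neurons than of later ones, and the neuronal gene Stmn2 in a smaller share. Whether tanycyte cells or RNA among the P8 neurons account for falls with age was not tested. The edgeR quasi-likelihood adjusted p ranged from 4.49e-05 (Cox6a2) to 0.0160 (Fabp7).

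Notch genes fell in 7 of 11 cases (9 adjusted over the list alone), proneural and precursor genes in 7 of 12 (9 adjusted over the list alone), S phase genes in 7 of 16 (13 adjusted over the list alone) and neural stem genes in 6 of 9 (7 adjusted over the list alone). Neuropeptide and monoamine genes rose in 6 of 15 cases and fell in 1 (8 and 2 adjusted over the list alone). In this order the camera adjusted p were 3.34e-05, 0.000232, 1.64e-05, 0.000148 and 0.0170, and 0.553 to 0.558 with an estimated correlation. Of the genes of the neuron-type lists with the highest level, Gad2, which makes GABA, rose (0.44) and Dlx1 fell (-0.33). Dlx2 (-0.26), Prox1 (-0.21), Nkx2-1 (-0.19), Isl1 (0.27) and Dlx6os1 (-0.15) did not pass, with means of 160.9, 158 and 156 CPM for Dlx2, Prox1 and Nkx2-1, 107 CPM for Isl1 and 101 CPM for Dlx6os1. In control neurons, of which there were 526, 44 and 12, the mean level was 61.4 CPM for Cartpt (at most 100), 257 ± 5.97 CPM for Npy and 154 ± 128 CPM for Gad2 (SD, n = 3).

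In all, 1586 of 14186 genes passed edgeR's test, 878 higher and 708 lower with age. The count was 893 without KO P8, 4500 without KO P17, 333 without KO P45 replicate 1 and 167 without replicate 2. Gad2 and Dlx1 lost their calls without either P45 replicate, Gad2 also without KO P8, and Hes5, Crym and Fabp7 lost theirs without replicate 2. Without KO P8 the values were -0.67 for Hes5, -0.78 for Crym, -0.75 for Fabp7 and 0.26 for Gad2. There Prox1 (-0.48) and Nkx2-1 (-0.59) passed, and Isl1, which did not pass, turned to -0.23.

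Astrocytes were the other type with enough cells in each library. Dlk1 rose from 16.5 ± 4.92 to 242 ± 119 CPM (n = 3 and 4), Tubb3 82.8-fold, Meg3 5.13-fold, Celf4 4.97-fold and Usp29 3.84-fold. Clec3b (7.64-fold), S100a4 (6.45-fold), Mia (4.49-fold), Hr (4.47-fold) and the potassium channel gene Kcnk1 (3.63-fold) fell. Clec3b, S100a4 and Mia were also among the largest falls in tanycytes. Whether tanycyte RNA among the astrocytes accounts for their falls here was not tested. Pan-neuronal genes rose in 5 of 11 cases, GABAergic genes in 5 of 6 and proneural and precursor genes in 4 of 9 (6, 6 and 6 adjusted over the list alone), with camera adjusted p of 5.27e-09, 1.22e-07 and 7.97e-06 and 0.405 for each with an estimated correlation. Neuron-specific transcripts were here those over 20-fold lower in control astrocytes than in KO-labelled neurons. The 50 most abundant of them stood in KO-labelled astrocytes at a median of 4.65% to 15.6% of their level in neurons. Astrocyte genes fell in 3 of 12 cases (9 adjusted over the list alone; camera adjusted p = 0.000290, and 0.421 with an estimated correlation): Slc1a2, Agt and Atp1b2, by 0.95, 0.96 and 0.68 on the log2 scale.

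In astrocytes 575 of 11046 genes passed edgeR's quasi-likelihood test, 285 higher and 290 lower, with adjusted p of the named genes from 5.36e-11 (Dlk1) to 0.0305 (Celf4). The count was 891 without a filter, 304 with DESeq2, 98 and 104 without the control or KO P17 library, 135 without control P45 and 344 without KO P45 replicate 1. Meg3 lost its call without control P45 or either KO P45 replicate, Celf4 without control P17 or P45, and Kcnk1 without control P17. Kcnk1 stood at -1.24 there, and Hr at -3.92 without control P45.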

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

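The interaction of the shares with age and the fits without proliferating tanycytes were tests chosen only after the results were seen. Each result here had a genotype effect that differed between ages by a test of the difference itself, per doubling of the postnatal day.

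In tanycytes, edgeR's interaction coefficients were 3.73 for Ube2c, 3.98 for Pbk, 2.89 for Cdk1, 3.91 for Mki67, 2.28 for Spc25, 2.12 for Prc1, 1.58 for Lockd and 1.44 for Opcml. They were negative for Kcne1l (-1.03) and Slc4a4 (-0.79). Among shares of cells, that of neurons had a coefficient of 2.30 (SE 0.56, edgeR adjusted p = 0.00648) and that of ependymal cells -1.39 (SE 0.48, edgeR adjusted p = 0.0443).

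For the cell cycle transcripts, a candidate explanation is a larger share of cells annotated as proliferating in the KO-labelled libraries. Left out, these cells took 15 of the 35 called S, G2 and M phase genes below the threshold or the filter, and 20 stayed called and higher (9 S phase and 11 G2 and M phase genes). The median log2 fold change, averaged over ages, was 3.58 over the 35 genes and 0.99 over the 34 still tested. The annotated cells themselves thus do not hold the whole average rise. Their RNA, free or in doublets, would stay in the other tanycytes and was not tested. The larger share therefore stays open as a source of the average rise. For the change with age it stays open too. Without these cells the coefficients went to 0.55 for Pbk, 1.12 for Mki67, 1.67 for Ube2c, 0.65 for Cdk1, 0.24 for Spc25, 0.74 for Prc1 and 0.63 for Lockd, and all 7 calls ended. Cells in the cycle that the annotation placed elsewhere, and a genotype effect within other tanycytes, stay open and were not tested.

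For the 50 genes of this interaction, 2 of the 24 splits of the 7 libraries that could be fitted gave as many, the real one included, and the highest other gave 4862. Chance is not excluded. That split puts both P8 libraries with control P45 and KO P17. It has no contrast at P8, and the genotype contrast has opposite signs at P17 and P45. Its calls may thus come from the genotype effect itself, which was not tested.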

How the results depend on the processing

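Leaving out proliferating tanycytes, and the list test without called doublets, were chosen only after the results were seen; the other settings here were fixed before. No paired analysis was possible because the control groups hold a single library each and the groups compared share fewer than 2 replicate numbers. Over 3474 values of single genes, gene lists and shares under the alternatives, 2924 stayed on their side of the threshold, 503 kept the direction and lost the call and 47 kept the direction and gained one. Of the values called in either setting 0 changed direction. Among values called in neither, Ddx3y, Isl1 in KO neurons and the ependymal share changed sign under some alternatives, as did the Notch, Sonic hedgehog, BMP and TGF-beta, microglia and macrophage and sex-linked lists.

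The number of genes called in tanycytes, KO against control, stayed within 1.5 times of 5260 under every alternative but leaving out a library, from 3851 with equal subtype proportions to 6203 with DESeq2, and was 1142 to 7161 with a library left out. The subtype counts behaved likewise, with 670 to 2810 for alpha1, 1226 to 5999 for alpha2, 1071 to 4127 for beta1 and 606 to 2391 for beta2. With fewer libraries, fewer residual degrees of freedom are left. With age as a factor, a library left alone at its age is fitted exactly and adds nothing to the genotype effect. Leaving out control or KO at P8 thus removes the same contrast, as does leaving out either at P17, and these are not separate checks. Leaving out either P8 library raised these counts. Among the 5260 genes called in tanycytes the median log2 difference was smallest in KO P8. It was 0.61 there and 1.19, 1.21 and 1.12 in the later KO-labelled libraries, a comparison made after results were seen. Whether this smaller difference is the cause was not tested.

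The change of the genotype effect with age was called for 92 genes without a filter, 360 with DESeq2, 1 with limma voom and 107 with age rank, and for 9 to 1450 with a library left out. P45 against P8 gave 1803 genes with DESeq2, 980 without proliferating tanycytes and 0 to 1791 with a library left out (the 0, by edgeR, had 2742 genes at an unadjusted p under 0.05). KO neurons with age gave 167 to 4500 with a library left out. Astrocytes gave 891 without a filter, 304 with DESeq2 and 98 to 810 with a library left out. For these the cause was not tested beyond the number of libraries.

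Of the 28 gene lists, 13 were called at the preset correlation, 0 by camera with an estimated correlation and 3 by fry, which asks another question (S phase, alpha tanycyte and Notch). The estimated correlations reach 0.913 (G2 and M phase), which widens camera's variance. Of the 9 cell type shares 4 were called, and 0 to 7 with a library left out. Restricting the shares to the neuroepithelial lineage was not run, because no annotated type lies outside it.

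Depth limits the rare classes: control P45 holds 12 neurons and 4 proliferating tanycytes, and KO P45 replicate 1 has the lowest median depth, 3839 UMIs per cell.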

Other observations

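The comparisons of neurons, ependymal cells and OPCs, the effect per age and both tests on NFI transcripts were chosen only after results were seen, as were the genes named in the first 2 paragraphs.

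With a minimum of 10 cells per library, 3 further cell types could be compared between KO-labelled and control libraries by edgeR's quasi-likelihood test. In ependymal cells 94 of 6457 genes passed, 36 higher and 58 lower. Dlk1 (log2 fold change 6.36), Pcp4 (3.23) and Peg3 (1.85) rose, as did the neuronal genes Tubb3 (5.09), Stmn3 (1.78), Gng3 (3.15) and Mllt11 (2.42), for which RNA from neurons was not tested here. S100a4 (-2.59), Gsn (-1.95), Mia (-1.73) and Gfap (-1.80) fell, as did the ependymal genes Rarres2 (-0.61) and Ccdc153 (-0.63). In OPCs 65 of 9526 genes passed, 46 higher and 19 lower. Cell division genes were among those that rose, such as Birc5 (3.67), Ccnb1 (4.06), Aurkb (4.36) and Mki67 (3.13). Meg3 (2.30) and the neuronal gene Stmn2 (2.83) rose too, while Spry2 (-1.28), Etv4 (-1.44) and Vegfa (-1.38) fell. Scrublet called 9.69%, 10.6%, 22.2% and 0% of OPCs in KO P8, P17 and P45 replicates 1 and 2. In controls it called 4.13%, 6.67% and 3.17% by age. Whether cells or RNA of other types account for the changes in OPCs was not tested. The TMM-scaled level of Mki67 in OPCs was 127.5 CPM in KO P8, 16.8 in KO P17, and 48.6 and 0 in the 2 KO P45 libraries, which hold 18 and 20 OPCs.

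In neurons 23 of 13938 genes passed, 10 higher and 13 lower, with only 12 neurons in control P45. The transcription factor genes Bcl11b (4.52) and Foxd1 (3.31) and the Notch modifier Mfng (3.04) were higher in KO-labelled neurons. Tbx3 (-2.36), Kitl (-2.74), Cldn10 (-4.15), Cryab (-7.17), Mia (-3.90), Clu (-2.18) and Adcy2 (-2.69) were lower. Tanycytes or other glia express several of these genes, at least Cryab, Mia, Clu and Adcy2. With each cell thinned to 2000 UMIs, the tanycyte gene Rax was seen in 20.5%, 22.7% and 45.5% of control neurons at P8, P17 and P45, and in 19.4%, 10.6%, 9.05% and 10.3% of neurons in KO P8, P17 and P45 replicates 1 and 2. The neuronal gene Stmn2 was seen in 79.7%, 68.2% and 27.3% of control neurons, the last being 3 of 11 cells, and in 35.9%, 77.7%, 73.5% and 73.5% of KO-labelled ones. Whether cells or RNA of another type in the control neurons account for these differences was not tested.

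Among the 5260 genes called in tanycytes, the median log2 difference from the control of the same age, in the fitted direction, was 0.61 in KO P8, 1.19 in KO P17 and 1.21 and 1.12 in the 2 KO P45 libraries. The genes were called from these same libraries, so these differences are no separate test of the effect. Cga stood at 20.7 TMM-scaled CPM in the tanycytes of KO P45 replicate 1 and at most 1.28 CPM in the other libraries. Xist stood at 1646 CPM and Ddx3y at 13.4 CPM in KO P45 replicate 2, against 515 and 56.5 CPM in replicate 1.

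Neuronal transcripts were higher in KO-labelled tanycytes and astrocytes. A candidate explanation is RNA carried over from neurons, free or in doublets. Carry-over was scaled by the median ratio of the 50 most abundant neuron-specific genes. The neuron-list genes under test were not kept out of these 50, so for any gene in both sets the outcome is partly set in advance. At this scale it equals a median of 91.8% of the difference over the 28 called neuron-list genes in tanycytes (quartiles 31.6 to 137). In astrocytes it equals 95.2% over 17 genes. The ratio was measured in the same KO-labelled tanycytes and astrocytes, with no separate measure of background RNA. Neuronal transcripts made by these cells would raise it too, so the values cannot tell carry-over from a genotype effect. Carry-over at this scale gives under 50% for 11 tanycyte genes, among them Meg3 (11.8%), Sox14 (7.59%), Nr4a2 (7.14%), Sox4 (30.7%) and Mfng (27.6%). Nr4a2 and Sox14 had higher mean levels in KO-labelled tanycytes (20.3 and 14.1 CPM) than in KO-labelled neurons (12.6 and 10.4 CPM). Carry-over of average neuron RNA alone would not give those levels. All other called neuron-list genes, Meg3 included, had lower mean levels in the tanycytes than in the neurons. A genotype effect stays open and untested for all of these genes. Doublets that Scrublet calls cannot be told apart from the rest: 22 of the 28 genes stayed called without them and the median log2 fold change went from 3.19 to 2.44, while Scrublet called 8.34%, 10.8%, 5.28% and 4.46% of tanycytes in the KO-labelled and 2.80%, 1.78% and 0.138% in the control libraries.

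Nfia, Nfib and Nfix transcripts were higher in KO-labelled tanycytes. A shift in subtype proportions is argued against, since 11 of the 12 tests of 3 genes in 4 subtypes gave a called rise. Carry-over from neurons is argued against too at P17 and P45. Of the 12 pairs of gene and KO-labelled library 9 had a lower CPM in neurons than in tanycytes, all of them in the P17 and P45 libraries. In KO P8 all 3 genes were higher in neurons: Nfia 809 against 647 CPM, Nfib 992 against 827 and Nfix 1212 against 932. This comparison of levels does not argue against carry-over there. The 50 neuron-specific genes, however, stood in KO P8 tanycytes at a median of 6.64% of their level in neurons (quartiles 5.29 to 8.33). Control P8 tanycytes held 389, 507 and 615 CPM of Nfia, Nfib and Nfix. At that ratio, carry-over at P8 is smaller than the rise, a comparison of 1 library per genotype. Transcripts that keep their 3′ end after recombination, swapped labels and a change in transcription or stability stay open, as the floxed exons are not given.

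Other splits of the 7 libraries were refitted, 34 of them estimable. For tanycytes 2 splits gave as many calls, the real one included (5260, highest other 5830), as did 2 for alpha2 tanycytes (4549, highest other 4567), 2 for astrocytes (575, highest other 732) and 2 for shares (4, highest other 7), so chance is not excluded there. Nor is it for the gene lists, where 8 splits did (13, highest other 17). For alpha1 (1 split; 1824, highest other 1431), beta1 (1 split; 3063, highest other 3043) and beta2 tanycytes (1 split; 1684, highest other 1422) only the real split gave as many. That share is under 0.05, but the splits ignore age, and the 12 arrangements within age allow no share under 0.0833, so chance is not excluded within age. Except for the lists, the highest other split was the one that puts KO P8 with the 3 controls, in which the P8 pair carries no contrast. For tanycytes and each subtype the next highest split gave 0 genes by edgeR.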
